A study of Mus musculus with 6 samples.

How the data were processed

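Total RNA from snap-frozen livers was extracted with Trizol and made into libraries with a standard Illumina protocol, per the labels' protocols. The strand setting and the read length are not given in the sources used here. The authors deposited 1 table for the whole series, in TPM (transcript abundance per fixed total), with Ensembl gene identifiers, symbols and 1 column per library. Each column of deposited TPM values sums to the same fixed total. The submitters' processing notes name STAR 2.6.1c, RSEM, edgeR and the genome build mm10, with no role or order given for the tools. STAR is an aligner, and RSEM, as a quantifier, shares ambiguous reads among genes, so near-identical genes such as the Mup family, Cyp2a4 and Cyp2a5, glutathione transferases and the Serpina1 genes have uncertain single values. Mitochondrially encoded genes likewise share sequence with nuclear pseudogenes, 4 of which (Gm10925, Gm28661, Gm29216 and Gm28437) held 8.56 ± 0.37% of TPM in controls and 9.62 ± 1.11% in the labelled knockout. TPM divides by transcript length and by the library's own total, so a gene's value falls or rises when abundant genes take more or less of that total. No read totals are kept, so the depth, counting intervals and detection limits are unknown here, and no count model was used.

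Gene identifiers were matched to GENCODE M21 on GRCm38, the assembly also called mm10, for positions and lengths. Of 55536 identifiers, 55450 matched, each with the same symbol, and 86 did not. Column names matched the sample titles, and 0 columns were left unmapped. Groups were taken from the labels, with 3 control libraries (null virus) and 3 labelled VMP1 knockout libraries (Cre virus).

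Genes with at least 1 TPM in at least 3 libraries were tested, 12796 in all. This filter admits genes low in all controls only if they are higher in the labelled knockout, so counts per list were also taken with no filter beyond a TPM above 0 in at least 1 library. Log2(TPM + 1) values were fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend and robust variances, and Benjamini-Hochberg adjustment at 0.05. The main model used TPM as deposited and no replicate block. Gene lists, 39 in number, were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. A list was tested if it had at least 3 tested members. Camera, which compares a list with all other tested genes, was run with a preset correlation of 0.01 and again with an estimated one, and fry was run beside it. Library measures were compared with two-sided exact permutation tests over all assignments of 3 libraries to each group. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

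The rule for named genes took Vmp1 and the 8 called genes with the largest increase and the 8 with the largest decrease. These had to have a mean of at least 5 TPM and groups that did not overlap, and predicted genes were left out. It added up to 3 called members of each pathway or cell type list with the largest change, at most 2 names from each other list, and 12 genes named whatever their result. These 12 were Apob, Mttp, Tm6sf2, Tmem41b, Sqstm1, Alb, Adgre1, Col1a1, Plin2, Hspa5, Ddit3 and Nqo1. The rule also allowed up to 2 uncalled members per list. These are given only as the count that remains from the members tested, a choice made after their values were seen, since 1650 uncalled genes turned lower with median-of-ratios scaling. Cyp2a5, Afp, Clec4f and Timd4 fall outside the rule and were chosen after their values were seen. A called gene that the rule names is not reported here. Some marker genes are also expressed by hepatocytes, among them Krt8, Krt18, Cxcl12, Hgf, Ecm1, Lpl, Thrsp, Car3, Cidec, Plin1, Sox4, Onecut1, Ggt1 and G0s2.

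The procedure was tested on simulated data built, for both groups, from the control means and the spread within groups, with 100 genes changed by each fold size. In a simulated comparison of 10940 genes it recovered 92% of genes changed by a log2 fold of 1 and 99% of those changed by 2, with 11 false calls (5.45% of calls). In a second simulation of 11942 genes, the 60 most abundant genes were lowered 8-fold and the total held fixed. There, 95% of the unchanged genes were called as simulated and 0.156% after median-of-ratios scaling. Most genes were unchanged by construction, which is what median-of-ratios scaling assumes. The simulation therefore cannot show which scaling is right for the real libraries.

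Alternatives changed the pseudocount, the filter, the scaling between libraries, the variance model, the threshold and the replicate number as a block, and left out each library in turn. Scalings were median-of-ratios, quantile normalization, and rescaling without mitochondrially encoded genes and the 20 most abundant genes. Rescaling without the Mup genes, and counting genes called in the same direction with both scalings, were added after seeing the data.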

Results

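RNA from 6 mouse liver samples was sequenced, 1 library per sample. C57BL/6 mice aged 8 to 10 weeks carried floxed Vmp1 alleles, in which Cre recombinase removes the part of the gene between its loxP sites. They received an intravenous adeno-associated virus of serotype AAV8, which infects liver efficiently. Its cargo was driven by the TBG promoter, a promoter active in hepatocytes. The virus carried no transgene in 3 control samples and Cre recombinase in the 3 samples labelled as hepatocyte-specific VMP1 knockout, and livers were taken after 2 weeks. VMP1 is a membrane protein of the endoplasmic reticulum that acts in autophagy and lipid handling. The series title concerns hepatic lipoprotein secretion and steatohepatitis, a fatty liver disease with inflammation, so the comparison asks which liver transcripts differ once Vmp1 is targeted. Expression is given as TPM, a length-corrected transcript abundance scaled to the same total in each library, for 55536 genes. TPM keeps no read number, so the depth is unknown. Values below are means ± SD with n = 3 libraries per group. Fold changes are on the log2(TPM + 1) scale ± SE, labelled knockout minus control, with Benjamini-Hochberg adjusted p from limma. The pseudocount of 1 understates the change of low genes. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

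The targeted gene was not lower in the libraries labelled VMP1 knockout. Vmp1 (ENSMUSG00000018171, GRCm38 chromosome 11, 86583865 to 86683836, minus strand, protein-coding) was at 70.7, 96.5 and 88.6 TPM in the 3 control libraries and at 157, 136 and 137 TPM in the 3 labelled knockout libraries. The log2 fold change of Vmp1 was 0.75 ± 0.13 with adjusted p = 3.8e-04 as deposited, and with median-of-ratios scaling it turned to -0.18 ± 0.12 with adjusted p = 0.2. With quantile normalization it was 0.23 with adjusted p = 0.072. Vmp1 stayed higher rescaled without the most abundant and mitochondrial genes (0.56, adjusted p = 0.0016) and without the Mup genes (0.49, adjusted p = 0.0049). The table holds 1 value per gene, and the annotation gives Vmp1 8 transcripts of up to 12 exons. Reads from exons left in place after Cre would still count at the gene, so the gene-level value does not check the deletion, and the exons that are floxed are not given in the sources used here. Cells other than hepatocytes would also keep the intact gene. Because the value goes against the label, the libraries are called labelled knockout throughout, and every direction below rests on the labels. The gene for the microRNA Mir21a lies inside the annotated Vmp1 gene and was listed at 0 in all 6 libraries. A processed pseudogene inside Vmp1, Gm11478, was at 1.33, 1.8 and 1.81 TPM in the controls and 8.53, 6.85 and 9.23 TPM in the labelled knockout, and reads of overlapping genes cannot be assigned with certainty.

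The livers labelled VMP1 knockout differed from the controls in most expressed genes. Many products of differentiated hepatocytes fell, and most inflammatory, interferon, matrix and antioxidant genes on the lists rose. The 22 major urinary protein genes (Mup), a hepatocyte-secreted family, held 16.9 ± 4.85% against 0.41 ± 0.117% of the TPM, controls first, and albumin (Alb) alone held 2.9 ± 0.663% against 1.16 ± 0.165%. In the same order, the 100 most abundant genes of each library held 64.6 ± 2.61% against 47 ± 1.66%. Genes with at least 1 TPM numbered 10940 ± 116 in the controls and 12940 ± 88.7 in the labelled knockout. For each of these 4 measures the groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give.

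Of 12796 genes tested, 10906 were called at an adjusted p under 0.05, of which 9537 were higher and 1369 lower in the labelled knockout (87.4% higher). Median-of-ratios scaling, which sets the middle gene to no change, lowered the log2 fold changes by a median of 0.83 and gave 4496 higher and 4689 lower (48.9% higher). Under quantile normalization 4520 were higher and 4534 lower. The median log2 fold change was 0.77 as deposited and -0.01 after median-of-ratios scaling. Of the genes higher as deposited, 4496 stayed higher, 3371 lost the call and 1670 turned lower. All 1369 lower genes stayed lower, and 1650 uncalled genes became lower. Since this scaling lowers log2 fold changes, a gene lower as deposited could hardly do otherwise. In the lists below, a call kept with both scalings therefore tests the higher calls and adds no support to the lower ones. Relative to the shift itself, 4496 genes rose and 4689 fell. Genes called in the same direction with both scalings numbered 5865, and the lower ones among them are only the 1369 lower as deposited. Of the 5865, 1680 rose and 640 fell by at least 1 log2 unit in both. The groups did not overlap in 11106 genes, 86.8% of those tested, where random labels would give 10% for a single gene. The filter fixed this for 1614 genes under 1 TPM in every control and 158 in every labelled knockout library. The shift shared by most genes can separate many others together, so the 10% is not a fair reference for the count.

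**Figure D1:**
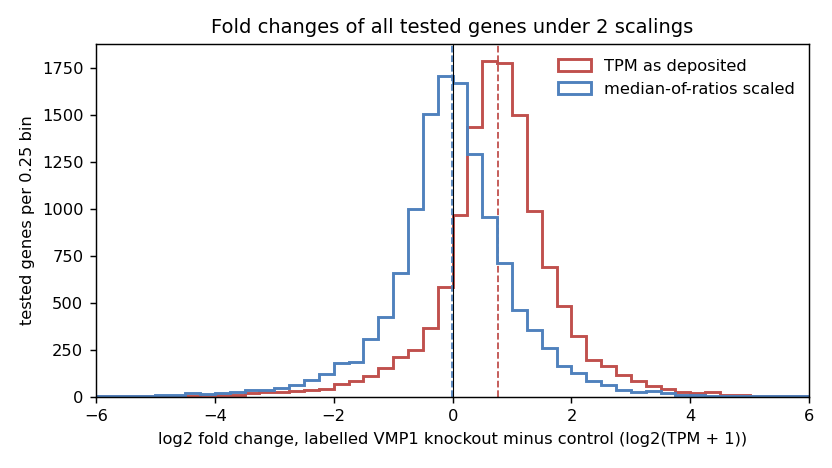
Histogram of the log2 fold change of the 12796 tested genes, labelled VMP1 knockout minus control, in bins of 0.25, with TPM as deposited (red) and after median-of-ratios scaling (blue). Dashed lines mark the medians, 0.77 and -0.01, and the x axis is limited to 6 on either side of 0, leaving out the most extreme genes.

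The largest increases included Cyp2a4, which encodes a steroid hydroxylase more abundant in female than in male mouse liver. Cyp2a4 went from 1.37 ± 0.35 to 2332 ± 317 TPM, a log2 fold change of 9.94 ± 0.14. Chemokine gene Ccl5 went from 0.793 ± 0.3 to 1446 ± 500.3 TPM. The others were Sprr1a, a small proline-rich protein gene, at 8.09, glutathione transferase gene Gsta1 at 7.91 and carbonyl reductase gene Cbr3 at 7.82. Ly6d rose by 7.75, the antiviral gene Rsad2 by 7.75 and the beta-defensin gene Defb1 by 7.63 on the log2 scale. The adjusted p of these 8 genes ranged from 2.0e-10 for Cbr3 to 4.8e-07 for Ccl5. Cyp2a4 has a near-identical neighbour, Cyp2a5, named here after its values were seen. Cyp2a5 rose from 1307 ± 677 to 11433 ± 854 TPM, and the assignment of reads between the 2 genes is uncertain. The same holds for Gsta1 and its paralog Gsta2.

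The largest decreases lay mostly in the Mup family. Mup17 (chromosome 4, 61591929 to 61595871) fell from 8667 ± 4979 to 20.3 ± 16.6 TPM (log2 fold change -8.76 ± 0.88, adjusted p = 4.2e-04). Mup19 changed by -8.46, Mup11 by -8.14, Mup2 by -7.63 and Mup16 by -7.40. Mup15 was at 2991, 366 and 5508 TPM in the controls and listed at 0 in all 3 labelled knockout libraries, so no fold is given. These genes are nearly identical in sequence, so the value of a single member is uncertain. Outside the family, the sulfotransferase gene Sult2a8 fell from 360.1 ± 1.58 to 1.15 ± 0.837 TPM, a log2 fold change of -7.46 ± 0.24. Carbonic anhydrase gene Car3 fell from 1076 ± 223 to 6.98 ± 5.25 TPM, a log2 fold change of -7.30 ± 0.59.

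Genes were also read by lists, with a limit on the list tests. Camera, which compares a list with all other genes, with its preset correlation called 25 of 38 lists, 10 higher and 15 lower, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05. No list (0) was called with an estimated correlation under any of the 19 settings run, so every camera call below, with any scaling or library left out, was made with the preset correlation. Other splits of the 6 libraries into groups of 3 gave up to 28 camera calls. Each of them mixes both groups and keeps part of their difference, so they do not measure camera's false calls. The counts of members that rose or fell are given beside camera's p, and rest on the same correlated genes. Each count is to be read against the share over all tested genes. As deposited 74.5% were higher and 10.7% lower, and with median-of-ratios scaling 35.1% and 36.6%. Lists with more members higher than lower can still lie below the 74.5%. Among them as deposited were the cholesterol, phospholipid, lipid droplet, autophagy, chaperone, ATF4 and immediate early lists. The lysosome list, with 30 of 36 higher, was little above it. The counts of members depend in part on the filter, since a gene under 1 TPM in every control library was tested only if it was higher in the labelled knockout. Of the 12796 tested genes 1614 were of this kind, and 158 were under 1 TPM in every labelled knockout library. With 1 labelled knockout library left out, genes under 1 TPM in every control could not be tested, which left 11141 to 11152 genes. For a list call lost or gained there, the filter and the library cannot be told apart. With no filter 12636 genes were higher and 1625 lower of 28532. Counts with no filter are given below for the lists where many members were of this kind. Fry, which asks only whether a list's genes move one way, called 31 lists, 23 higher and 8 lower. Adjusted over the list alone, the counts of higher and lower members equalled those over all genes tested, except in 6 lists. These were lipoprotein genes (9 and 17), fatty acid oxidation (2 and 20), chaperones (14 and 5), B cells (8 and 0), mitochondrially encoded genes (0 and 4) and nuclear oxidative phosphorylation genes (8 and 0).

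Genes of very-low-density lipoprotein (VLDL) assembly and plasma lipoproteins moved both ways, with more lower than higher. Apob (ENSMUSG00000020609, chromosome 12, 7977648 to 8016835), which encodes the structural protein of VLDL, fell from 1022 ± 37.6 to 505 ± 15.2 TPM, a log2 fold change of -1.01 ± 0.10 with adjusted p = 1.1e-05. The carboxylesterase gene Ces1d, linked to lipid mobilization for VLDL, fell by 3.74 and Apoa2 fell by 2.41 on the log2 scale. Apoa4 rose by 1.92. Of 34 tested members, 10 rose and 17 fell, and with median-of-ratios scaling 2 of the 10 and all 17 kept their call and direction. With that scaling alone 2 were higher and 27 lower, and with quantile normalization 4 and 21. In the same libraries 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose. Mttp (chromosome 3, 138089854 to 138144968), the triglyceride transfer protein that lipidates apolipoprotein B, was at 69.6 ± 2.93 in controls and 73.8 ± 5.75 TPM, a log2 fold change of 0.08 ± 0.10 with adjusted p = 0.44, and turned to -0.85 with median-of-ratios scaling. Tm6sf2, which acts in VLDL lipidation, was at 18 ± 3.44 in controls and 27.5 ± 7.05 TPM, with a log2 fold change of 0.57 ± 0.19 and adjusted p = 0.021. Its value turned to -0.33 with median-of-ratios scaling, and its call was lost without control replicate 1 (0.55, adjusted p = 0.06) or 3 (0.46, adjusted p = 0.076). Tmem41b, a scramblase related to VMP1, was higher by 0.43 ± 0.11 as deposited and lower (-0.45) with median-of-ratios scaling. Set against all other genes the list was lower by camera (adjusted p = 2.5e-10), with adjusted p = 0.21 with an estimated correlation.

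**Figure D2:**
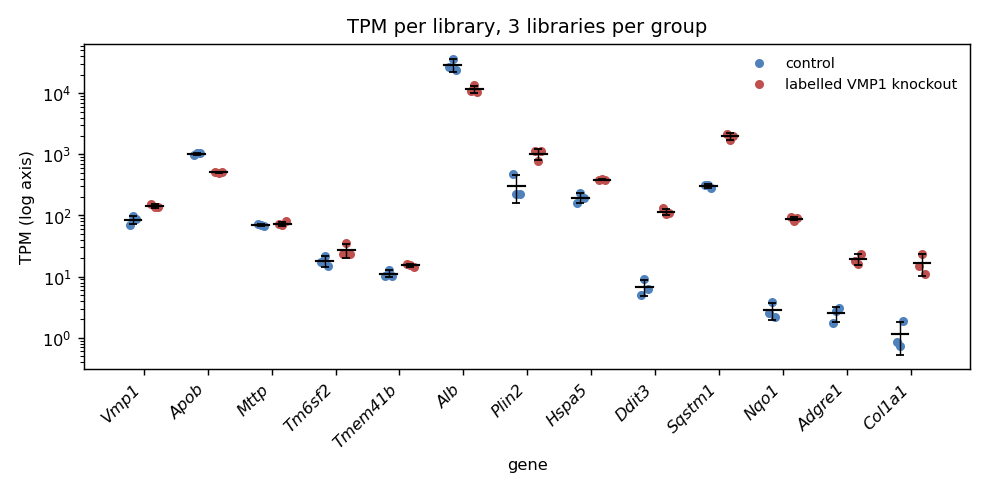
TPM of Vmp1 and the 12 genes named whatever their result, on a log axis, in 3 control (blue) and 3 labelled VMP1 knockout (red) libraries. Points are libraries, bars are group means and error bars are 1 SD; Apob fell from a mean of 1022 to 505 TPM, and Vmp1, Tm6sf2, Tmem41b and Hspa5, higher here, lost the call or turned lower with median-of-ratios scaling, while Hspa5 stayed higher with quantile normalization.

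Sterol and fatty acid synthesis genes moved both ways as deposited. In the same libraries 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose. Among 25 cholesterol biosynthesis genes, 14 rose and 5 fell as deposited, and 2 and 5 did so with both scalings. With median-of-ratios scaling alone 2 were higher and 12 lower, and with quantile normalization 6 and 8. The sterol carrier gene Stard4 fell from 17.4 ± 2.33 to 5.51 ± 0.267 TPM. Lanosterol synthase gene Lss rose by 1.26 as deposited and was 0.36 with median-of-ratios scaling, where it was not called. The list's median was 0.66, below the median of all genes, and camera placed it lower (adjusted p = 0.045, and adjusted p = 0.67 with an estimated correlation). That call was lost with median-of-ratios scaling (adjusted p = 0.077) and without labelled knockout replicate 1 (0.099), 2 (0.56) or 3 (0.083). Of 21 fatty acid and triglyceride synthesis genes, 9 rose and 6 fell as deposited, and 0 and 6 did so with both scalings. With median-of-ratios scaling alone 0 were higher and 15 lower, and with quantile normalization 1 and 11. Mlxipl, the glucose-responsive transcription factor ChREBP, fell by 1.24 and the desaturase gene Fads2 fell by 1.13 on the log2 scale. Acyl-CoA synthetase gene Acsl5 rose by 1.08 as deposited, was 0.14 and not called with median-of-ratios scaling, and stayed higher with quantile normalization (0.72, adjusted p = 4.5e-04). Camera gave adjusted p = 4.2e-04 for a lower list, and adjusted p = 0.54 with an estimated correlation. Its median was -0.03.

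Most fatty acid oxidation and ketogenesis genes fell, in libraries where 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose. Of 30 tested, 21 fell and 2 rose, and the same 21 and 2 did so with both scalings. The fatty acid omega-hydroxylase genes Cyp4a10, a target of the nuclear receptor PPARalpha, and Cyp4a12a, a male-biased gene, had log2 fold changes of -4.04 and -3.49. Pdk4, whose kinase restrains the use of pyruvate, went the other way and rose from 1.41 ± 0.754 to 22.5 ± 8.71 TPM, a log2 fold change of 3.26 ± 0.34. The list's median log2 fold change was -0.77, lower by camera with adjusted p = 2.0e-21, and adjusted p = 0.2 with an estimated correlation.

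Phospholipid and lipid droplet genes also moved both ways, while 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose. Among 20 phospholipid synthesis and remodelling genes, 14 rose and 4 fell as deposited, and 6 and 4 did so with both scalings. Ethanolamine kinase gene Etnk2 fell by 1.91 on the log2 scale, while the acyltransferase gene Lpcat2 rose by 1.58 and choline kinase gene Chka by 1.55. The median of this list was 0.68, and camera did not call it (direction lower, adjusted p = 0.32). Of 20 lipid droplet genes, 11 rose and 7 fell as deposited, and 8 and 7 did so with both scalings. The fatty acid uptake gene Cd36 rose from 7.78 ± 1.61 to 179.7 ± 17 TPM, a log2 fold change of 4.37 ± 0.14. Hilpda, an inhibitor of lipolysis, rose by 4.06 and fatty acid binding protein gene Fabp4, also expressed by macrophages, rose by 3.06. Plin2, which coats lipid droplets, rose from 308 ± 147 to 1023 ± 216 TPM, a log2 fold change of 1.80 ± 0.34 with adjusted p = 0.0022. The droplet list's median was positive (0.65) while camera placed it lower (adjusted p = 0.031, and adjusted p = 0.54 with an estimated correlation). The call made with the preset correlation was lost without labelled knockout replicate 1 (adjusted p = 0.051) or 2 (0.086), and with median-of-ratios scaling (0.65).

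Sqstm1 and most lysosomal genes rose, while most calls among autophagy machinery genes depended on the scaling. Sqstm1 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827) encodes p62, an autophagy cargo receptor and itself an NRF2 target. Its TPM rose from 306 ± 22.5 to 1963 ± 236, a log2 fold change of 2.67 ± 0.13 with adjusted p = 1.2e-07. Map1lc3a rose by 1.47 and Atg4b by 1.29 on the log2 scale. Of 39 autophagy genes, 25 rose and 6 fell as deposited, and with median-of-ratios scaling 27 were lower and 4 higher. With quantile normalization 23 were lower and 8 higher. Their median was 0.45, camera placed the list lower without calling it (adjusted p = 0.14), and with median-of-ratios scaling it was called lower (adjusted p = 4.4e-04, and adjusted p = 0.22 with an estimated correlation). Of 36 lysosome and TFEB target genes, 30 rose and 1 fell, and 21 and 1 did so with both scalings. Cathepsin D gene Ctsd rose from 135 ± 21.3 to 822 ± 78.2 TPM. The leading member, Gpnmb, rose by 5.87 and is also a macrophage marker, and the proton pump subunit gene Atp6v0d2 rose from 0.433 ± 0.318 to 7.88 ± 2.8 TPM. Macrophage markers rose in the same libraries, 26 of 28. The lysosome list was higher by camera with adjusted p = 0.031, and adjusted p = 0.67 with an estimated correlation.

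Targets of ATF4 and CHOP, transcription factors of the integrated stress response, were called higher about as often as all tested genes as deposited. Their median change was larger. Chaperones of the endoplasmic reticulum were higher or lower depending on the scaling. Of 30 chaperone and unfolded protein response genes, 15 rose and 5 fell as deposited, and with median-of-ratios scaling 0 were higher and 24 lower. With quantile normalization 2 were higher and 17 lower. Hspa5, the chaperone BiP, was at 196 ± 37.4 in controls and 383 ± 8.54 TPM, a log2 fold change of 0.99 ± 0.14 as deposited. With median-of-ratios scaling Hspa5 was at 0.04 and not called, and with quantile normalization it stayed higher (0.62, adjusted p = 0.0011). Herpud1 and Ero1lb fell, with log2 fold changes of -1.68 and -1.33. Derl1 rose by 1.11, was 0.19 and not called with median-of-ratios scaling, and stayed higher with quantile normalization (0.45, adjusted p = 0.0018). The median was positive (0.28), while camera placed the list lower (adjusted p = 0.0064, and adjusted p = 0.54 with an estimated correlation). Of 26 ATF4 and CHOP targets, 18 rose and 2 fell, and 16 and 2 did so with both scalings, while 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose in the same libraries. As deposited 74.5% of all tested genes were higher, so the count of 18 does not set this list apart from other genes. Its median log2 fold change was 1.57, against 0.77 for all tested genes. Of the 26 targets, 5 were under 1 TPM in every control. With median-of-ratios scaling the medians were 0.97 and -0.01. With median-of-ratios scaling 35.1% of all tested genes were higher. Ddit3, which encodes CHOP, rose from 6.78 ± 2.04 to 116 ± 14 TPM, a log2 fold change of 3.93 ± 0.18 with adjusted p = 2.8e-07. Nupr1 rose by 5.86, the serine synthesis gene Psat1 by 4.72 and Atf3 by 4.02. Camera did not call this list (adjusted p = 0.32), but called it higher with median-of-ratios scaling (adjusted p = 0.0034). The adjusted p with an estimated correlation was 0.62 as deposited and 0.22 with that scaling.

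Most targets of NRF2, the transcription factor of the antioxidant response, rose, in libraries where 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers also rose. Of 38 tested, 34 rose and 2 fell, and 30 and 2 did so with both scalings. The quinone reductase gene Nqo1 rose from 2.84 ± 0.9 to 89 ± 6.19 TPM, a log2 fold change of 4.57 ± 0.16 with adjusted p = 3.5e-08. Sulfiredoxin gene Srxn1 rose from 15.9 ± 1.88 to 1053 ± 224 TPM, and Gsta1 and Cbr3, named above, also belong to this list. The median was 2.47, higher by camera with adjusted p = 7.5e-04, and adjusted p = 0.54 with an estimated correlation. Glutathione transferase genes have close paralogs, so their single values are uncertain.

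Most hepatocyte identity, bile acid and cytochrome P450 genes fell, in libraries where 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose. Of 37 hepatocyte identity and secreted protein genes, 28 fell and 1 rose, all in the same direction with both scalings. Alb fell from 29032 ± 6631 to 11605 ± 1651 TPM, a log2 fold change of -1.31 ± 0.19 with adjusted p = 1.4e-04. Serpina1c, of a family with close paralogs, fell by 3.27, the xenobiotic receptor gene Nr1i3 fell by 3.21 and the urea cycle gene Otc fell by 2.63 on the log2 scale. Of 29 bile acid genes, 18 fell and 6 rose, and 18 and 4 did so with both scalings. Cyp8b1, needed for cholic acid synthesis, fell from 180.5 ± 23.4 to 1.25 ± 0.653 TPM and the sinusoidal uptake transporter gene Slco1a1 fell from 110.1 ± 11 to 0.383 ± 0.138 TPM. Abcc4, which encodes a basolateral export pump, rose by 5.17. Of 33 P450 and drug metabolism genes, 22 fell and 5 rose, and 22 and 3 did so with both scalings. Cyp2c54 and Cyp2c37 fell, with log2 fold changes of -5.74 and -5.63, against the rise of Cyp2a4. Camera gave adjusted p = 8.2e-26, 9.3e-14 and 9.7e-18 for these 3 lists, all lower. With an estimated correlation the adjusted p was 0.17 for each.

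Inflammatory and interferon genes rose together with markers of immune cells. Of 31 cytokine, chemokine and adhesion genes, 27 rose and 3 fell, and 25 and 3 did so with both scalings. Of these 31, 12 were under 1 TPM in every control, and with no filter 31 of 35 rose and 3 fell. After Ccl5, the leading members were Cxcl10, from 1.91 ± 0.231 to 370.4 ± 57.3 TPM, and the monocyte chemokine gene Ccl2, from 0.277 ± 0.118 to 127 ± 32.4 TPM. All 34 interferon-stimulated genes rose as deposited, and with median-of-ratios scaling 27 stayed higher and 3 turned lower. Rsad2 led this list, followed by Oasl1 at 6.94 and Ifit2 at 6.17. Of 28 macrophage and Kupffer cell markers, 26 rose and 1 fell, and 26 and 1 did so with both scalings. The filter removed 0 of these markers, though 11 were under 1 TPM in every control. Adgre1, which encodes F4/80, rose from 2.51 ± 0.673 to 19.3 ± 3.88 TPM, a log2 fold change of 2.53 ± 0.18 with adjusted p = 1.9e-06. Cd14 rose by 6.50, Lgals3 by 5.90 and Gpnmb by the value given above. Neutrophil markers S100a9 and S100a8 rose by 3.26 and 3.23. Of 16 neutrophil markers 11 were not tested and 3 of the other 5 were under 1 TPM in every control, so the count of 4 higher among 5 was largely set by the filter. With no filter 10 of 16 were higher and 1 lower. G0s2 fell by 2.24 and is also a hepatocyte lipolysis inhibitor. Of 20 T and NK cell markers 12 were not tested, and the 8 tested were all under 1 TPM in every control, so the filter fixed their direction. Among them Gzma rose by 1.82, Trbc2 by 1.67 and Klrk1 by 1.59, and with no filter 20 of 20 were higher. With quantile normalization 4 of the 8 were higher. Of 14 B and plasma cell markers 6 were not tested, and 6 of the 8 tested were under 1 TPM in every control. Jchain rose by 3.30, Iglc2 by 1.78 and Cd79a by 1.06, 7 of the 8 rose with both scalings, and with no filter 12 of 14 were higher. With quantile normalization only 2 of the 8 were higher, and Cd79a was not called (0.20, adjusted p = 0.13).

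Camera called the inflammatory list (adjusted p = 0.031), the interferon list (1.4e-04) and the macrophage list (5.8e-04) higher. With an estimated correlation the adjusted p was 0.57, 0.54 and 0.5. The inflammatory call was lost without control replicate 2 (adjusted p = 0.083) or labelled knockout replicate 1 (0.15), 2 (0.25) or 3 (0.14). Without a labelled knockout library the 12 inflammatory members under 1 TPM in every control were not tested, so the filter may underlie those losses. The neutrophil, T and NK cell, and B cell lists were not called (adjusted p = 0.84, 0.13 and 0.15), and the latter 2 were called higher with median-of-ratios scaling (0.0044 and 0.01). These 2 had adjusted p = 0.67 and 0.62 with an estimated correlation as deposited, and 0.42 and 0.38 with that scaling.

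Extracellular matrix genes rose together with markers of stellate cells and of the other non-parenchymal cells. Of 36 matrix and stellate activation genes 35 were tested and rose, 34 of them with both scalings, but 13 were under 1 TPM in every control and could only be higher. The other 22 all rose, 21 with both scalings, and with no filter 36 of 36 rose. Col1a1, of fibrillar collagen, rose from 1.15 ± 0.623 to 16.7 ± 6.41 TPM, a log2 fold change of 3.01 ± 0.31 with adjusted p = 1.0e-04. The macrophage metalloelastase gene Mmp12 led the list at 6.89, followed by the contractile genes Acta2 at 4.23 and Tagln at 4.09. Of 19 quiescent stellate cell markers, 18 rose and 1 fell, and 17 and 1 did so with both scalings. Nt5e rose from 1.17 ± 0.323 to 26.7 ± 10.7 TPM, Dcn by 2.15 and Lrat by 1.94 on the log2 scale. All 24 endothelial markers rose, 18 with both scalings, led by Lyve1 at 2.98, Stab1 at 2.16 and Cdh5 at 1.97. Of 18 cholangiocyte and ductular markers, 16 rose and 1 fell, and 16 and 1 did so with both scalings. As 11 of these 18 were under 1 TPM in every control, the count without a filter is of more use, 20 of 24 higher and 1 lower. Cldn4 rose by 3.49, Krt23 by 3.07 and Krt8, also a hepatocyte keratin, by 2.88.

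Blood and fat markers moved both ways. Of 7 tested erythroid and blood genes, 3 rose and 1 fell, and 1 and 1 did so with both scalings. The erythroid heme synthesis gene Alas2 fell by 3.20 on the log2 scale. The platelet gene Pf4 rose by 2.01 and Bpgm rose by 0.81 as deposited but was -0.061, not called, with median-of-ratios scaling. Of 7 adipocyte markers, 3 rose and 4 fell with both scalings, including Car3 above, Lpl at 3.16 and Cidec at 2.28. Only Cela1 of the 20 pancreatic acinar genes passed the filter, and it fell by 0.87. Camera gave adjusted p = 8.9e-05 for the matrix list and 0.0072 for the endothelial list, both higher, and 0.019 for the adipocyte list, lower. With an estimated correlation the adjusted p was 0.45, 0.62 and 0.24. The stellate (adjusted p = 0.064), cholangiocyte (0.091) and blood (0.33) lists were not called. A stellate call appeared without labelled knockout replicate 1 (adjusted p = 0.028), 2 (0.032) or 3 (0.034), where the adjusted p with an estimated correlation was 0.63, 0.48 and 0.51. In these 3 runs genes under 1 TPM in every control, 2 of the 19 stellate markers among them, were not tested. With median-of-ratios scaling the stellate (8.0e-04) and cholangiocyte (6.8e-04) lists were called higher and the adipocyte call was lost (adjusted p = 0.52). The stellate and cholangiocyte lists had adjusted p = 0.32 and 0.33 with that scaling and an estimated correlation.

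Proliferation and p53 target genes mostly rose, in libraries where 26 of 28 macrophage markers also rose. Of 36 cell cycle genes, 34 rose and 1 fell, and 29 and 1 did so with both scalings. Of these 36, 21 were under 1 TPM in every control and could only be higher, and among the other 15, 13 rose and 1 fell, 9 rising with both scalings. With no filter 38 of 40 rose and 1 fell. Ube2c rose from 0.49 ± 0.0721 to 6.83 ± 1.98 TPM, Mcm6 from 1.16 ± 0.0751 to 9.72 ± 1.57 TPM and Top2a from 0.457 ± 0.15 to 5.97 ± 2.07 TPM. Of 31 p53 and cell death genes, 29 rose and 0 fell, and with median-of-ratios scaling 25 were higher and 2 lower. In this list 7 were under 1 TPM in every control, and of the other 24, 22 rose. The cell cycle inhibitor gene Cdkn1a rose from 1.74 ± 0.589 to 79.4 ± 12.5 TPM, a log2 fold change of 4.88 ± 0.17. Phlda3 rose by 4.46 and Bcl2a1b, expressed in immune cells, by 3.90. Camera gave adjusted p = 0.014 for the cell cycle list and 5.5e-04 for the p53 list, both higher. With an estimated correlation the adjusted p was 0.67 and 0.35. The cell cycle call was lost without labelled knockout replicate 2 (adjusted p = 0.16) or 3 (0.096). The 21 members under 1 TPM in every control were not tested there, so the filter may underlie these losses.

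**Figure D3:**
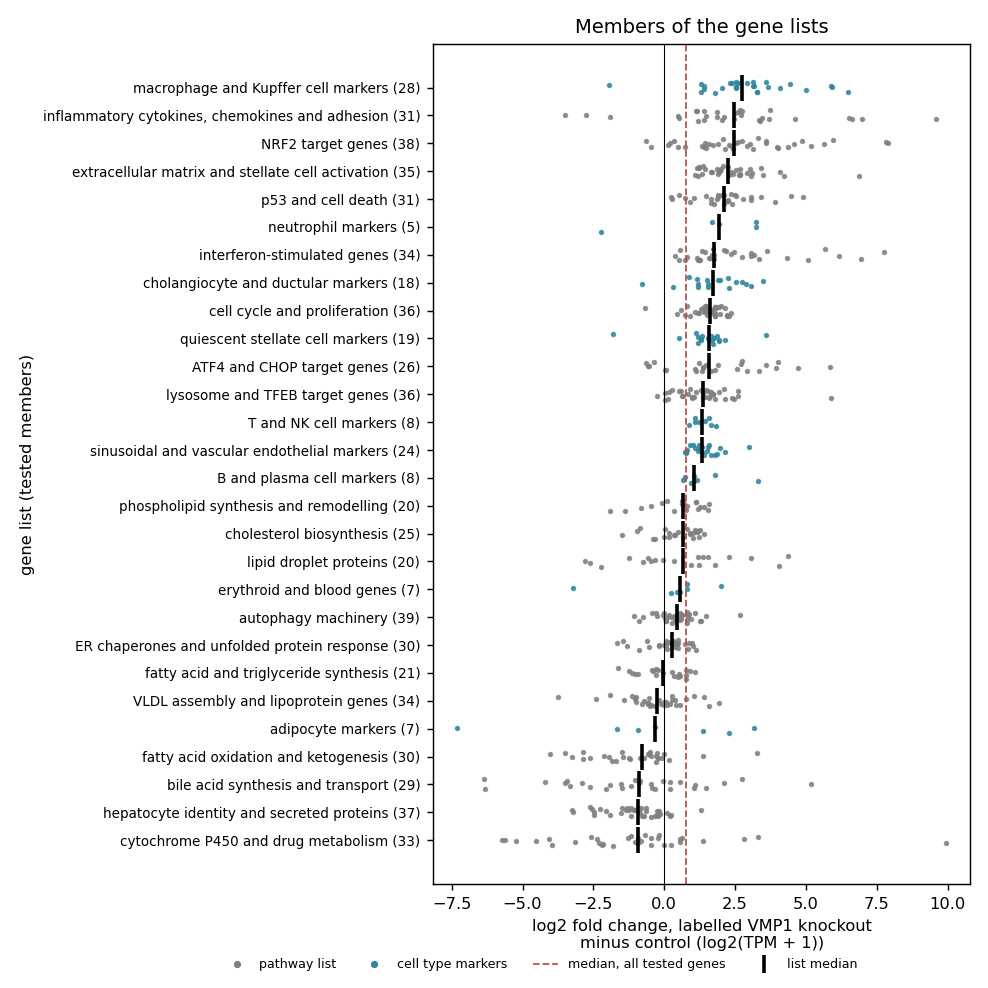
Log2 fold change, labelled VMP1 knockout minus control, of each tested member of the pathway lists (grey points) and cell type marker lists (teal points), with TPM as deposited. Black bars are list medians, the red dashed line is the median of all tested genes (0.77) and numbers in parentheses are tested members; the macrophage median is 2.76 and that of P450 genes -0.93, and since median-of-ratios scaling lowers genes by a median of 0.83, many points between 0 and the dashed line are lower there.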

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

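The counts of genes called in the same direction with both scalings, and the rescaling without the Mup genes, were added after seeing the data. Of 126 named genes other than Vmp1, 84 were tested under all 20 alternatives, and 70 of these kept their direction and side of the threshold under each. The other 42 were left out of some, mainly those without a labelled knockout library, and all 15 sign changes came with another scaling. Most of the named genes were picked for a large change in these same data. Uncalled list members were left out after their values were seen. The count of 70 therefore does not show how stable genes in general were. Of 33 lists run under all 19 of their alternatives, 1 kept camera's direction and call. The estimated correlation is among the 19 and by itself removed all 25 calls, so no called list could be kept. The losses named above for single lists cover only median-of-ratios scaling and libraries left out. Camera calls with the preset correlation were also lost for 5 lists with the mean TPM filter, 4 with quantile normalization and 3 with no filter. Array weights and rescaling without the Mup genes lost 2 each, and a pseudocount of 5 and the replicate block 1 each. Of 12796 genes, 10906 were called. The mean TPM filter gave 7218, since it tests fewer genes (8428), the added log2 fold change threshold of 1 gave 5395, and both scalings gave 5865. Genes higher numbered 6209 with the mean filter, 4496 with median-of-ratios scaling, 4520 with quantile normalization, 4755 with the fold threshold and 4496 with both scalings. Genes lower numbered 4689, 4534 and 640 with median-of-ratios scaling, quantile normalization and the fold threshold. With the Mup genes left out 8415 were higher and 1899 lower. Leaving out 1 library gave between 8836 and 10734 calls. Vmp1 was -0.18 with median-of-ratios scaling and 0.23 with quantile normalization. With an estimated correlation camera called 0 lists, with 8 at an unadjusted p under 0.05, against 31 called by fry. Values that turned negative with median-of-ratios scaling were Mttp at -0.85, Tm6sf2 at -0.33, Tmem41b at -0.45, Bpgm at -0.061, Eif2s3y at -0.44, Ddx3y at -0.53, Ndufa2 at -0.14 and Cycs at -0.39. With quantile normalization Mttp was -0.55, Tm6sf2 -0.19, Tmem41b -0.37, Eif2s3y -0.23 and Ddx3y -0.46. Mttp was -0.11 rescaled without the most abundant and mitochondrial genes and -0.18 rescaled without the Mup genes. These follow from the scaling itself, which lowers most genes together. Camera's direction, for lists it never called there, turned for phospholipid synthesis and remodelling (adjusted p = 0.70) and autophagy machinery (0.77) with no filter. It turned for neutrophil markers with the mean TPM filter (0.65), with array weights (0.99) and without control replicate 2, with a leave-one-out range of 0.876 to 0.967 over the controls, since too few markers were tested without a labelled knockout library. For sex chromosome genes it turned without labelled knockout replicate 2, with a range of 0.679 to 0.994. The cause of these turns was not tested. A replicate block gave 10760 calls, 9427 higher and 1333 lower. Same-numbered libraries deviated together with r = 0.0762, 0.0397 and -0.115 across genes, so the numbers were not taken as pairs. Depth is unknown, so its effect on low genes could not be assessed.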

Other observations

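Sex-biased, zonal, clock and housekeeping genes also moved, in libraries where 26 of 28 macrophage, 24 of 24 endothelial and 18 of 19 stellate markers rose. Of 19 male-biased liver genes 18 fell with both scalings, with Serpina1e down from 10685 ± 1356 to 95.3 ± 51 TPM and Hsd3b5 from 139 ± 16.8 to 0.223 ± 0.292 TPM. Of 9 female-biased genes 4 rose and 2 fell, and 3 and 2 did so with both scalings, with Cyp2a4 up and Cyp4a14 at -2.85 on the log2 scale. The Y-linked genes Eif2s3y (24.2 to 39 TPM) and Ddx3y (10.1 to 14.9 TPM) were present in all 6 libraries, so each held RNA of male tissue. Eif2s3y (0.48) and Ddx3y (0.34) were higher as deposited and lower with median-of-ratios scaling (-0.44 and -0.53). Of the 4 tested sex chromosome genes 3 were higher as deposited and all 4 lower with that scaling. The Ddx3y call was lost without labelled knockout replicate 1 (0.27, adjusted p = 0.069) or 3 (0.32, adjusted p = 0.053). Of 19 periportal genes 12 fell and 4 rose, and 12 and 1 did so with both scalings, with the gluconeogenic gene Pck1 at -3.66 and Aldh1b1 at 1.89 as deposited and not called with median-of-ratios scaling (0.97), but higher with quantile normalization (1.22, adjusted p = 0.038). Of 22 pericentral genes 11 fell and 7 rose, and 11 and 2 did so with both scalings, with Cyp2c37 lower and Gstm3 up from 119 ± 22.4 to 5937 ± 222 TPM. Clock genes included 9 lower and 4 higher of 18, and 9 and 1 with both scalings, with the output gene Dbp at -2.52 and Usp2 at -2.40. The hours of collection are not given in the sources used here.

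All 35 cytosolic ribosomal protein genes rose, 34 with both scalings, with Rplp0 at 2.14 and Rps24 at 2.12. Nuclear genes of oxidative phosphorylation, in contrast, included 10 higher of 29 as deposited and 28 lower with median-of-ratios scaling, where Ndufa2 (0.79) and Cycs (0.55) turned to -0.14 and -0.39. With quantile normalization 1 was higher and 14 lower, Ndufa2 stayed higher (0.34, adjusted p = 0.015) and Cycs was not called (0.06, adjusted p = 0.58). Of 13 mitochondrially encoded genes 5 fell as deposited, with mt-Co3 at -1.02 and mt-Nd2 at -0.83, and all 13 were lower with median-of-ratios scaling. With quantile normalization 4 were higher and 5 lower, and mt-Nd2 was not called (-0.10, adjusted p = 0.61), so this list has no direction that holds under each scaling. Nuclear pseudogenes share their sequence, so these values are uncertain. Immediate early and heat shock genes included 15 higher and 2 lower of 23, and 9 and 2 with both scalings, with Fosl1 up from 0.0133 ± 0.0231 to 15.7 ± 7.38 TPM and Atf3 given above. Camera called the periportal (adjusted p = 1.5e-09), pericentral (9.2e-08), male-biased (4.4e-24), clock (2.4e-07) and mitochondrially encoded (7.3e-07) lists lower and the ribosomal list (6.0e-04) higher. With an estimated correlation the adjusted p was 0.29, 0.21, 0.17, 0.17, 0.35 and 0.67. The female-biased (adjusted p = 0.054), sex chromosome (0.84), immediate early (0.64) and oxidative phosphorylation (0.0502) lists were not called. Set against all other genes, the female-biased list was called lower without control replicate 1 (0.049), 2 (0.04) or 3 (0.018) or labelled knockout replicate 2 (0.022). The adjusted p with an estimated correlation was then 0.65, 0.57, 0.54 and 0.57. The oxidative phosphorylation list was likewise called lower without control replicate 1 (0.0075) or 3 (0.022) or labelled knockout replicate 2 (0.046), and with median-of-ratios scaling (1.5e-06). There the adjusted p with an estimated correlation was 0.68, 0.65, 0.78 and 0.43. Afp, the fetal albumin-like gene, was chosen after its values were seen and rose from 0.54 ± 0.171 to 45.8 ± 10.5 TPM, a log2 fold change of 4.90 ± 0.17. The Kupffer cell genes Clec4f and Timd4, chosen likewise, rose by 2.54 and 1.30, and Timd4 was not called with quantile normalization (0.45, adjusted p = 0.053).

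Of the tests that follow, those on the hepatocyte share, on blood, on the scaling of Vmp1 and on a swapped library were chosen only after the result they bear on was seen. The first pattern is the excess of higher calls, 9537 against 1369. Loss of the Mup transcripts from a fixed total does not account for all of it, since without them the median log2 fold change was 0.56 ± 0.032 (SE over libraries). The same holds for the 100 most abundant genes, without which it was 0.31 ± 0.028, and for transcript length, since the lowest median over 5 equal groups of genes by length was 0.70. A fall in the share of more transcripts than these, or more RNA per cell for most genes, may underlie the rest, and TPM alone does not separate them.

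The samples can be split into groups of 3 in 10 ways. By limma the real split called 10906 genes, 9537 higher and 1369 lower, and each of these counts was reached in 1 split, the real one, with 0 as the highest of the others. For lists called by camera the real value was 25 and the highest other 28, and 3 of the 10 splits, the real one included, gave as many. With 10 splits no share under 0.05 can be reached. Every split but the real one mixes both groups and keeps part of their difference, so these counts do not measure false calls.

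The second pattern is the rise of macrophage, stellate and endothelial markers. A lower share of hepatocyte RNA would raise them alike, but the mean macrophage marker rose by 1.56 ± 0.076 (SE) log2 units more than the mean endothelial marker, and by 2.02 ± 0.093 with a pseudocount of 0.1. The mean stellate and endothelial markers rose nearly alike, by 1.45 and 1.39 log2 units, so that pair does not speak against a lower hepatocyte share. More blood left in the tissue would raise globin genes at least as much, but macrophage markers rose by 2.45 ± 0.30 log2 units more than the 4 globin genes, which rose by 0.51. More macrophages, or a changed state of those present, may account for the difference, which was not tested. The part of the rise that all these cell types share may still come from a lower hepatocyte share.

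The third pattern is the higher Vmp1 value in the libraries labelled VMP1 knockout. Scaling of the libraries is a candidate explanation for part or all of the rise, since Vmp1 was -0.18 ± 0.12 (SE) with median-of-ratios scaling and 0.23 ± 0.10 with quantile normalization, but it leaves open why Vmp1 did not fall. Vmp1 stayed higher rescaled without the most abundant and mitochondrial genes (0.56) or the Mup genes (0.49), where the median of all tested genes was also still above 0 (0.65 and 0.56). A single library swapped between the groups is argued against by the correlations, of which the lowest within groups was 0.987 and the highest between groups 0.864. An exchange of the whole groups would leave these correlations the same, so they cannot address it. Reads of exons left after Cre may keep the value up, which cannot be told apart from an intact gene because the table holds 1 value for up to 12 exons, and a biological difference in Vmp1 transcription was not tested.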
